A study of Homo sapiens with 6 samples.

How the data were processed

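RNA-seq was made from HCT116 cells, a human colorectal carcinoma line, in 6 libraries: 3 from control cells and 3 from cells treated with 5aza. Per the labels' protocols, the treatment was 5 µM for 48 hours, followed by 48 hours in fresh medium, and RNA was extracted with an RNeasy kit and made into libraries by standard Illumina protocols. Strand marking and RNA selection are not given in the sources used here. The table's columns were matched to the samples through the sample descriptions. Both carry the code DAC, a common abbreviation of 5-aza-2'-deoxycytidine, where the titles and the treatment protocol have 5aza. The treatment is called 5aza here, as in the titles, and the compound's full name is not given in the sources used here.

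The values are FPKM per gene (fragments scaled to transcript length and to the library's number of mapped fragments), per the file headers, in 1 table deposited by the authors that holds all 6 libraries. The submitters' processing notes list STAR 2.5.1b, HTSeq 0.6.0 and DESeq2 1.10.1, and the builds GRCh38 and Rnor_6.0, with no role for any of them. The program that made the FPKM values is not given in the sources used here. The table has 16726 rows and 16715 distinct identifiers. For the 11 identifiers that occur more than once, the row with the higher mean was kept. Of the identifiers, 15451 are Ensembl genes, of which 15410 were matched to a symbol, and 1264 are unannotated genes named newGene with a number. For 88 identifiers all 6 values are 0. The Ensembl genes found in the annotation lie on autosomes, so genes of the X and Y chromosomes and the mitochondrial genome were not analysed here. The fixed list of mitochondrial genes therefore gave no values, and 1 of the 62 genes of the cancer-testis list, PRAME, was in the table. Coordinates are from GENCODE release 29 on GRCh38, looked up by Ensembl identifier for 15440 genes.

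The summed FPKM per library was 624311, 628399 and 601916 in control replicates 1 to 3, and 592051, 584739 and 577735 in 5aza replicates 1 to 3. Total read counts are not given in the sources used here. From the smallest steps between low values of 1292 genes with a single annotated transcript, the number of fragments was estimated at 34200000, 34800000 and 36900000 in the control libraries and 36100000, 36800000 and 35800000 in the 5aza libraries. For each library, the fragment length and depth were those with the best fit to whole reads, so the estimate is rough and may hold no information on depth. With these steps, 25.7% to 38.5% of low values lay within 0.1 of a whole number of reads. By chance 20% would at a fixed setting, and more at a setting chosen for its fit. Whole reads were therefore not recovered, and no test on counts was run. Depth gives no exact floor for a single gene, so no limit is printed for values listed at 0.

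Values were used as log2(FPKM + 0.1) with no further scaling. A fold change on this scale understates the change of genes near 0 FPKM. The 12360 genes with at least 0.5 FPKM in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend; two-sided), with Benjamini-Hochberg adjustment over all genes tested. A gene under 0.5 FPKM in all control libraries passed this filter only if all 3 5aza libraries reached 0.5 FPKM. In lists that hold such genes, counts, medians and set tests therefore cover members chosen partly by their rise. This weighs most in lists of mostly silent genes. A gene is said to have risen or fallen when its adjusted p was under 0.05. All adjusted p-values of single genes in the report are limma's. Changes of at least 2-fold are those with an absolute log2 fold change of 1 or more as well. Genes switched on were those under 0.1 FPKM in all 3 control libraries and at 1 FPKM or more in all 3 5aza libraries; this count rests on no test. Reported means are of FPKM, with their SD over 3 libraries, and SE is that of the log2 fold change.

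Of 21 gene lists with members in the table, those with at least 5 tested members were tested with camera (limma), with a preset correlation between genes of 0.01, adjusted over the 20 lists. Camera with an estimated correlation and fry, both in limma, were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes. The p with an estimated correlation is printed beside that with the preset one.

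Apart from those said below to be added or chosen later, the tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap and whose higher mean is at least 5 FPKM, leaving out unannotated genes and clone names; DNMT1, DNMT3A, DNMT3B and UHRF1; up to 2 rising and 2 falling members of each list with the largest changes; ACTB and GAPDH as control genes; and the 3 smallest adjusted p-values in each direction. It named 73 genes, not all of which are reported here. Genes named outside it were chosen after their values were seen.

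The scripts were tested on simulated data drawn from the means and spreads of the real libraries for the comparison of 5aza with control, with 12360 genes simulated and 12172 tested. Of 49 genes given a log2 change of 0.3, 46.9% were recovered, of 49 given 0.5, 71.4%, of 49 given 1, 91.8%, and of 48 given 2, 100%. Of 173 calls, 5 (2.89%) were false. In the simulation 11937 of the tested genes were left unchanged and the noise of each gene was drawn independently. In the real data 23.7% of genes tested were called and genes of 1 list move together. These shares may therefore not carry over to the real data.

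Alternatives tried were other pseudocounts, filters, scalings, variance models and thresholds, protein-coding genes alone, each library left out in turn with the genes tested held fixed, and the replicate number as a block. Removal of the trend of fold change on expression, of trends on GC content and length, and of the latter with the replicate block were added after the data were seen. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The table has 1 value per gene, so transcripts of 1 gene were not compared. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.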

Results

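The series asks how DNA methylation relates to the transcripts a cell makes, and measured RNA in HCT116 cells, a human colorectal carcinoma line, after 5aza. Azanucleosides such as 5aza are cytidine analogues that enter nucleic acids and trap DNA methyltransferases, so that methylation is lost as cells divide. There were 3 control and 3 5aza libraries. Each library's summed FPKM lay between 577735 and 628399, and the 10 most abundant genes took between 7.95% and 8.14% of it. Across genes, log2 values of libraries of the same group correlated at Pearson's r of 0.992 to 0.993, and those of different groups at 0.976 to 0.977. Genes are not independent replicates, so these correlations only describe the libraries. The first principal component held 67.3% of the variance and separated the groups. The number of rows listed at 0 was 1761, 1724 and 1663 in the control libraries, and 801, 755 and 783 in the 5aza libraries.

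The comparison of 5aza with control asks which genes change when DNA methyltransferases are blocked. The largest changes were increases from low levels: genes of chemokines, germline genes and genes known to be methylated in colorectal cancer rose from near 0 to several FPKM, and target genes of p53 rose together. Falls were smaller, and took in 40 of 44 DNA replication genes, 39 of 42 mitosis genes, 16 of 22 cholesterol synthesis genes and 31 of 55 splicing genes. Camera called these 4 lists with a preset correlation but not with an estimated correlation (adjusted p = 0.0644, 0.0633, 0.0512 and 0.0510). Fry, which does not compare a list with other genes, called all 4 (fry adjusted p = 2.40e-04 each). Of 12360 genes tested, 2929 (23.7%) changed, 1310 up and 1619 down, with limma and Benjamini-Hochberg adjustment. Changes of at least 2-fold were 268 rises and 6 falls, so that 97.8% of them were rises. These counts depend on the settings: quantile normalization gave 39 falls, a pseudocount of 1 gave 114 rises and 1 fall, and other filters on low values gave between 120 and 634 rises. The 6 falls were of the histone genes H4C3 and H2BC13 and 4 unannotated genes, newGene_1792, newGene_2300, newGene_2983 and newGene_3137, chosen after their values were seen. The groups did not overlap in 42.2% of genes tested, where chance gives 10%. Over all genes tested, the median log2 fold change was -0.01. Direction went with abundance. Of 940 genes with a mean under 1 FPKM, 183 rose and 5 fell, whereas of 926 genes at 100 FPKM or more, 52 rose and 375 fell. With the trend of fold change on expression removed, 1437 genes rose and 972 fell, so that rises made up 59.7% of calls in place of 44.7%. Calls numbered 1880 without control replicate 2 and 1877 without 5aza replicate 3, and falls numbered 1035, 940 and 987 without control replicate 1, control replicate 2 and 5aza replicate 3.

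**Figure D1:**
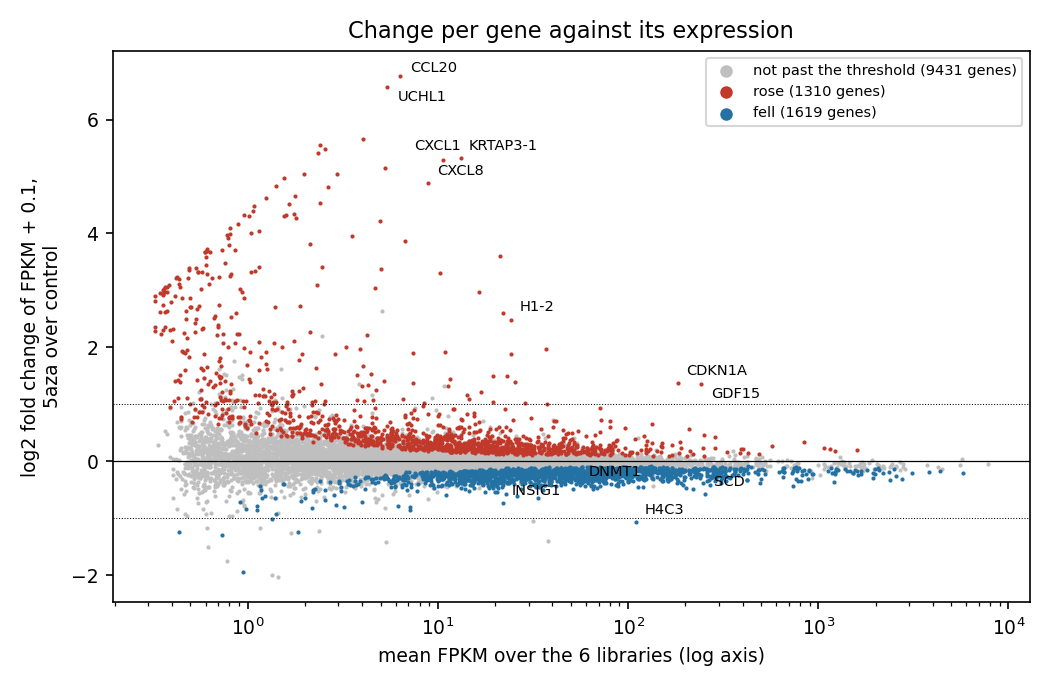
Log2 fold change (5aza minus control, on log2(FPKM + 0.1)) of each tested gene against its mean expression, with genes that rose in red, genes that fell in blue and some named genes labelled; dotted lines mark 2-fold changes. The 268 rises of at least 2-fold lie mostly at low expression, and 6 genes fell as far.

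Among annotated genes of at least 5 FPKM in the higher group, the largest rise in log2(FPKM + 0.1) was of CCL20 (ENSG00000115009, chromosome 2, 227805739 to 227817564), which encodes a chemokine that attracts CCR6-bearing lymphocytes. Its mean rose from 0.0195 ± 0.0338 to 12.6 ± 0.553 FPKM (SD, n = 3), a log2 change of 6.77 (SE 0.21, adjusted p = 2.48e-06). UCHL1 (ENSG00000154277, chromosome 4, 41256413 to 41268455), a ubiquitin hydrolase of neurons, rose from 0.0161 to 10.8 FPKM, a log2 change of 6.58. As a ratio of means, the rise of UCHL1 (674) was larger than that of CCL20 (647), so the pseudocount sets their order. The neutrophil chemokine genes CXCL1 and CXCL8 rose from 0.447 to 20.9 and from 0.499 to 17.3 FPKM. KRTAP3-1, a hair keratin-associated protein, rose from 0.560 to 25.7 FPKM, and ZFP42, a zinc finger gene of pluripotent cells, from 0.0789 to 5.79 FPKM. CLDN6, a claudin of embryonic epithelia, rose from 0.104 to 5.19 FPKM, and LCN2, which encodes the iron-siderophore binding protein lipocalin 2, from 0.428 to 9.47 FPKM. SPARC, a secreted matrix protein, rose from 0.810 to 12.5 FPKM and LGALS7B, a galectin, from 0.831 to 9.23 FPKM. An unannotated gene, newGene_956, had one of the smallest adjusted p-values (3.83e-07), with means of 3.15 and 39.3 FPKM. LGALS7B and KRTAP3-1 belong to families of near-identical copies, between which reads may have been split, so their values are uncertain.

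The falls were smaller. H4C3 (ENSG00000197061, chromosome 6, 26103876 to 26104310), a replication-dependent histone gene, fell from 149 ± 24.0 to 70.4 ± 2.41 FPKM (SD, n = 3; log2 change -1.07, SE 0.10). EFCAB2 fell by 0.85 on the log2 scale, RASGRP2, a guanine nucleotide exchange factor, by 0.80, and IMMP1L, a mitochondrial inner membrane peptidase subunit, by 0.61. The IMMP1L call was lost without control replicate 1 (adjusted p = 0.0773), control replicate 2 (0.0862), 5aza replicate 2 (0.0573) or 5aza replicate 3 (0.0673), and with no variance trend. NR2F1, a nuclear receptor, fell from 41.1 to 26.2 FPKM. SCD, the desaturase that makes monounsaturated fatty acids, fell from 306 ± 3.21 to 204 ± 1.24 FPKM (log2 change -0.58, SE 0.025, adjusted p = 1.14e-05) and, with CDT1 and NR2F1, had the smallest adjusted p-values among falls. FANCG, a Fanconi anaemia protein, fell from 24.3 to 16.6 FPKM, and DNAJB14 from 23.6 to 16.1 FPKM. The control genes ACTB (1728 and 1606 FPKM) and GAPDH (3812 and 3644 FPKM) did not pass the test, with log2 fold changes of -0.11 and -0.07. The sign turned to 0.02 for ACTB and 0.07 for GAPDH with the expression trend removed, and for GAPDH also to 0.05 under quantile normalization and 0.01 with GC and length trends removed; ACTB passed without control replicate 3 (adjusted p = 0.0479).

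DNMT1 (ENSG00000130816, chromosome 19, 10133345 to 10231286), the maintenance DNA methyltransferase that 5aza traps, fell from 64.0 ± 10.4 to 47.6 ± 1.35 FPKM (SD, n = 3; log2 change -0.41, SE 0.10, adjusted p = 0.0236). UHRF1, which brings DNMT1 to hemimethylated DNA, fell from 76.1 to 66.9 FPKM (log2 change -0.19, adjusted p = 0.0159). The de novo methyltransferase genes DNMT3A (3.74 and 4.31 FPKM, log2 fold change 0.20, adjusted p = 0.0906) and DNMT3B (9.82 and 9.27 FPKM, log2 fold change -0.08, adjusted p = 0.395) did not pass the test. The DNMT1 call was lost without control replicate 2 (adjusted p = 0.0539), 5aza replicate 1 (0.0679), 5aza replicate 2 (0.0558) or 5aza replicate 3 (0.0692), and with no variance trend (0.0629). The UHRF1 call was lost without control replicate 2 (adjusted p = 0.0554), and under quantile normalization (0.0568), with no variance trend (0.0516) and with the expression trend removed (0.0944). DNMT3A passed with no variance trend (adjusted p = 0.0355). Of 27 tested genes of DNA methylation and its readers and partners, 10 fell, 0 rose and 17 did not pass, and 11 fell adjusted over the list alone. HELLS, a chromatin remodeller needed for DNA methylation, fell from 35.3 to 25.9 FPKM. The list was lower than other genes with a preset correlation (camera adjusted p = 0.0295), but not with an estimated correlation (adjusted p = 0.171) or with no variance trend (adjusted p = 0.0572).

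Target genes of p53 rose nearly uniformly: of 37 tested, 35 rose, 1 fell and 1 did not pass, with the same counts of rises and falls adjusted over the list alone. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), the cell cycle inhibitor p21, rose from 101 ± 1.97 to 263 ± 2.03 FPKM (SD, n = 3; log2 change 1.38, SE 0.028, adjusted p = 3.83e-07), and GDF15, a stress cytokine, rose from 135 to 346 FPKM. MDM2, the ubiquitin ligase that degrades p53, rose from 24.8 to 49.8 FPKM and TP53I3, an oxidoreductase gene, from 9.30 to 19.9 FPKM; both were chosen after their values were seen. KITLG fell from 661 to 579 FPKM, a call lost with the expression trend removed (adjusted p = 0.198), and APAF1, chosen after its values were seen, had means of 5.44 and 5.82 FPKM (adjusted p = 0.434). Over the list, the median log2 fold change was 0.46 (camera adjusted p = 3.15e-24 with a preset correlation, and adjusted p = 0.00673 with an estimated correlation).

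Genes of cell division fell together. Of 44 tested DNA replication genes, 40 fell, 1 rose and 3 did not pass, and of 42 mitosis genes, 39 fell, 0 rose and 3 did not pass; the counts of rises and falls were the same adjusted over the list alone. MCM5, a subunit of the replicative helicase, fell from 137 to 101 FPKM, RFC4, a clamp loader subunit, from 68.8 to 50.5 FPKM, and CDT1, a licensing factor, from 73.1 ± 1.07 to 54.7 ± 0.604 FPKM (SD, n = 3; log2 change -0.42, SE 0.029, adjusted p = 1.39e-04). AURKB, a mitotic kinase, fell from 79.2 to 57.4 FPKM and CDCA3, a regulator of mitotic entry, from 23.6 to 17.3 FPKM. CCNE1, cyclin E1, rose from 24.9 to 27.3 FPKM with an adjusted p of 0.0482, a call lost without any 1 of the 6 libraries (adjusted p between 0.0693 and 0.132), with the replicate block and with no variance trend. The genes that did not pass, chosen after their values were seen, were POLA2, GINS4 and PRIM2 of replication and ASPM, MKI67 and CENPF of mitosis. The median log2 fold changes were -0.30 and -0.29 (camera adjusted p = 1.90e-19 and 2.38e-20). With an estimated correlation, both calls were lost, with adjusted p = 0.0644 for replication and adjusted p = 0.0633 for mitosis.

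Germline genes, which are silent in most adult tissues, were among those that rose from the lowest levels. Of 45 with values, 16 passed the filter on low values and were tested. Of these 16, 9 rose, 0 fell and 7 did not pass, and adjusted over the list alone 11 rose and 1 fell. DAZL, an RNA-binding protein of germ cells, rose from 0.00416 to 4.77 FPKM (log2 change 5.55, SE 0.18, adjusted p = 2.52e-06), and TUBA3D, a testis tubulin with near-identical copies, from 0.0648 to 3.13 FPKM. SYCP3, of the meiotic chromosome axis, rose from 0.0453 to 2.25 FPKM and MAEL, of the piRNA pathway, from 0.0478 to 1.66 FPKM; both were chosen after their values were seen. Over the 16 tested genes, the germline median log2 fold change was 1.81, or 1.14 under quantile normalization (camera adjusted p = 1.29e-06, and adjusted p = 0.0383 with an estimated correlation). Members silent in control libraries, such as DAZL and SYCP3, passed the filter through their 5aza values alone. The median and the set test are therefore partly fixed by that choice and do not describe the whole list. PRAME, the 1 cancer-testis antigen gene tested, rose from 28.8 to 38.4 FPKM (adjusted p = 6.76e-04).

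Of 44 genes with values that are known to be methylated in colorectal cancer, 26 passed the filter on low values and were tested. Of these 26, 13 rose, 1 fell and 12 did not pass, and adjusted over the list alone 15 rose and 1 fell. UCHL1 and SPARC led the list. VIM, an intermediate filament gene whose methylation is used as a colorectal cancer marker, rose from 6.13 ± 0.553 to 37.8 ± 2.78 FPKM (SD, n = 3), and was chosen after its values were seen. CDKN2A, whose products include the cell cycle inhibitor p16, fell as a gene from 90.8 to 73.4 FPKM, a call lost with GC and length trends removed (adjusted p = 0.0537). The median log2 fold change was 0.36 (camera adjusted p = 2.24e-06), and the call was lost with an estimated correlation (adjusted p = 0.0644). Members silent in control libraries, such as UCHL1 and FBN2, the latter chosen after its values were seen, passed the filter through their 5aza values alone. The median and the set test are therefore partly fixed by that choice and do not describe the whole list. Of 17 imprinted genes tested, 4 rose, 0 fell and 13 did not pass, with the same counts adjusted over the list alone. FAM50B rose from 1.04 to 2.18 FPKM and IGF2, a fetal growth factor, from 9.96 to 13.6 FPKM; the others, chosen after their values were seen, were BLCAP and PEG10. The imprinted list's camera adjusted p was 0.0194, and its adjusted p was 0.0942 with an estimated correlation and 0.0578 with the replicate block and GC and length trends removed.

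Interferon response genes rose in part: of 36 tested, 15 rose, 0 fell and 21 did not pass, and adjusted over the list alone 22 rose and 1 fell. IFI27 rose from 2.07 ± 1.20 to 18.4 ± 2.70 FPKM (SD, n = 3; log2 change 3.30, SE 0.45, adjusted p = 0.00249), and BST2, tetherin, from 2.25 to 6.61 FPKM. RIGI, a sensor of viral RNA that was chosen after its values were seen, rose from 2.91 to 4.52 FPKM. The interferon list had a median log2 fold change of 0.27 (camera adjusted p = 1.47e-07, and adjusted p = 0.0319 with an estimated correlation). Of 25 antigen presentation genes, 8 rose, 0 fell and 17 did not pass, with 9 rises adjusted over the list alone. CD74, the invariant chain of MHC class II, rose from 0.158 to 1.76 FPKM. PSMB8, of the immunoproteasome, rose from 0.421 to 0.952 FPKM, a call lost without control replicate 1 (adjusted p = 0.0789), control replicate 2 (0.109), 5aza replicate 1 (0.122) or 5aza replicate 3 (0.128) and under 4 other alternatives. B2M, the light chain of MHC class I, rose from 370 to 431 FPKM and was chosen after its values were seen. The list's camera adjusted p was 4.40e-04, and with an estimated correlation its adjusted p was 0.0827.

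Histone genes split. Of 30 tested, 14 rose, 3 fell and 13 did not pass, with the same rises and falls adjusted over the list alone. H1-2, a linker histone, rose from 7.30 ± 0.472 to 41.2 ± 1.08 FPKM (SD, n = 3; log2 change 2.48, SE 0.056, adjusted p = 5.80e-07), and H2BC12, chosen after its values were seen, from 14.9 to 58.8 FPKM. H4C8 rose from 0.265 to 1.49 FPKM, a call lost without control replicate 1 (adjusted p = 0.0748), control replicate 3 (0.0642), 5aza replicate 1 (0.0861) or 5aza replicate 2 (0.101), under quantile normalization and with no variance trend. Apart from H4C3, the falls were of H2BC13, from 1.08 to 0.381 FPKM, and of H1-10, chosen after its values were seen, from 217 to 174 FPKM. Most histone genes have near-identical copies, and transcripts of many lack a poly(A) tail, so their values depend on the library's RNA selection. Over the histone list, the median log2 fold change was 0.91, or 0.45 under quantile normalization (camera adjusted p = 7.02e-05), and with an estimated correlation the adjusted p was 0.0512.

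Cholesterol synthesis genes fell: of 22 tested, 16 fell, 0 rose and 6 did not pass, with 18 falls adjusted over the list alone. INSIG1, which holds back the sterol-sensing SREBP pathway and is its target, fell from 27.5 ± 1.61 to 16.4 ± 0.853 FPKM (SD, n = 3; log2 change -0.74, SE 0.059, adjusted p = 2.51e-04). The camera adjusted p was 3.76e-09, and with an estimated correlation the adjusted p was 0.0512. In the integrated stress and unfolded protein list, 4 of 28 genes rose, 9 fell and 15 did not pass, or 5 and 10 adjusted over the list alone. ATF3 rose from 7.32 ± 0.260 to 12.8 ± 0.607 FPKM (n = 3) and SESN2, also in the p53 list, from 7.53 to 10.1 FPKM; the other rises, chosen after their values were seen, were of DDIT4 and HSPA5. PHGDH, the first enzyme of serine synthesis, fell from 76.5 to 54.1 FPKM and ATF4, the transcription factor of the stress response, from 342 to 272 FPKM. The list did not pass (camera adjusted p = 0.111; 0.533 with an estimated correlation), except without control replicate 3 (adjusted p = 0.0454).

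Of 55 splicing factor genes, 31 fell, 2 rose and 22 did not pass, with 37 falls and 2 rises adjusted over the list alone. SNRPA, a U1 snRNP protein, fell from 98.9 ± 3.26 to 74.4 ± 2.07 FPKM (SD, n = 3) and CLK2, a kinase of SR proteins, from 21.5 to 16.5 FPKM. PTBP3 rose from 36.1 to 40.1 FPKM and MBNL2 from 24.6 to 27.1 FPKM. The PTBP3 call was lost without control replicate 1 (adjusted p = 0.0550) or control replicate 2 (0.0574) and with GC and length trends removed, and the MBNL2 call without any 1 library but control replicate 3 (0.0590 to 0.0936), with the replicate block and with no variance trend. The splicing list's median log2 fold change was -0.17, or -0.09 both under quantile normalization and with the expression trend removed (camera adjusted p = 2.71e-10), and with an estimated correlation the adjusted p was 0.0510. Of 72 ribosomal protein genes, 29 fell, 0 rose and 43 did not pass, with 36 falls adjusted over the list alone. RPS26 fell from 974 to 784 FPKM and RPS29 from 2641 to 2096 FPKM, the latter call being lost without control replicate 2 (adjusted p = 0.0534), 5aza replicate 2 (0.0641) or 5aza replicate 3 (0.0667), with no variance trend and with the expression trend removed. The ribosomal median of -0.14 went to -0.00028 under quantile normalization (adjusted p = 0.438) and -0.0026 with the expression trend removed (adjusted p = 0.567), and the camera adjusted p of 1.39e-10 became an adjusted p = 0.240 with an estimated correlation.

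Markers of cell types were also compared. Of 35 colon epithelial genes with values, 13 passed the filter on low values and were tested. Of these 13, 6 rose, 2 fell and 5 did not pass, with 7 rises and 2 falls adjusted over the list alone. ANPEP, an intestinal peptidase, rose from 0.00519 to 0.724 FPKM and KRT20, a keratin of differentiated colon cells, from 0.774 ± 0.173 to 3.07 ± 0.0303 FPKM (SD, n = 3). CA2 fell from 22.2 to 19.3 FPKM, a call lost without control replicate 2 (adjusted p = 0.0538). EPCAM fell from 166 to 153 FPKM, a call lost without control replicate 1 (adjusted p = 0.0700), control replicate 2 (0.0562), 5aza replicate 2 (0.0693) or 5aza replicate 3 (0.0716) and under 5 other alternatives. The genes that did not pass, chosen after their values were seen, were HNF4A, KLF4, CDX2, AXIN2 and DPP4. The list's camera adjusted p was 0.00290, and with an estimated correlation the adjusted p was 0.0644. ANPEP passed the filter through its 5aza values alone, so the set test is partly fixed by that choice. Of 25 mesenchymal genes with values, 11 were tested, of which 5 rose, 0 fell and 6 did not pass, with 6 rises adjusted over the list alone. COL6A3 rose from 0.0494 to 1.19 FPKM and ACTA2, also in the p53 list, from 3.15 to 6.16 FPKM; the others, chosen after their values were seen, were COL1A1, FN1 and MYL9. The camera adjusted p was 9.24e-04, and with an estimated correlation the adjusted p was 0.124. COL6A3 passed the filter through its 5aza values alone, so this set test is likewise partly fixed by that choice.

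Of 5 blood and endothelial markers tested, 1 rose, 0 fell and 4 did not pass. CD68, a lysosomal protein of macrophages, rose from 3.50 to 5.23 FPKM, a call lost without 5aza replicate 2 (adjusted p = 0.0507); the others, chosen after their values were seen, were HBA1, CD8A, HBG2 and HBA2. This list's median log2 fold change was -0.01 while its mean was 0.08 and camera gave an upward direction (adjusted p = 0.720; 0.767 with an estimated correlation), and it passed with no filter on low values (adjusted p = 0.0160). The median turned to 0.04 under quantile normalization, 0.03 with the expression trend removed and 0.05 with GC and length trends removed. Of 21 neuronal genes with values, 6 were tested. UCHL1, which passed the filter through its 5aza values alone, rose and 5 did not pass (camera adjusted p = 0.0832, or 0.207 with an estimated correlation). Those 5, chosen after their values were seen, were STX1A, MAP2, SYT1, GRIN1 and SCG2. The neuronal list passed without control replicate 3 (adjusted p = 0.0454) or 5aza replicate 2 (0.0300), with no filter on low values (0.0172) and by fry (4.16e-04). For both lists, counts adjusted over the list alone were the same.

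Where a list is said to have 0 rises or 0 falls in limma's test, the count in that direction at an unadjusted p under 0.05 was also 0, except for 2 rises among methylation genes and for 1 fall each among germline, interferon response and blood genes and 2 among imprinted genes. With the preset correlation, camera called 15 of the 20 lists. With an estimated correlation, it called the p53, interferon response and germline lists and none of the other 17 lists. For the colon epithelial and imprinted lists, the estimated correlations were 6.24e-04 and -0.0583, below the preset 0.01. A higher correlation therefore does not account for those lost calls. The p53 list, with an estimated correlation of 0.00399, also went from camera p = 1.58e-25 with the preset correlation to p = 3.37e-04 with the estimated one. The form with an estimated correlation thus gave weaker p-values even where the correlation was lower than the preset. For the other lists, a lost call is not in itself a sign of correlated genes. Fry, which does not compare a list with other genes, kept all the calls that the estimated correlation lost (fry adjusted p from 2.40e-04 to 0.0173).

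Of 5 metallothionein genes, which encode metal-binding proteins, MT1A rose from a value listed at 0 in all 3 control libraries to 2.34, 1.24 and 1.09 FPKM in the 5aza libraries. MT1F fell from 13.5 to 10.1 FPKM, a call lost without any 1 library but control replicate 3 (adjusted p between 0.0569 and 0.108) and under 5 other alternatives. MT2A, MT1X and MT1E, chosen after their values were seen, did not pass; adjusted over the list alone, 1 gene rose and 2 fell. For this list, the median log2 fold change was -0.12 (-0.02 under quantile normalization, -0.0087 with the expression trend removed, -0.04 with GC and length trends removed) and the mean 0.64, camera gave a downward direction (adjusted p = 0.468; 0.700 with an estimated correlation) and fry an upward one (adjusted p = 0.659). Camera turned upward under quantile normalization and with expression or GC and length trends removed. These genes are near-identical, so reads may be shared. Of 331 zinc finger genes of the ZNF series, 24 rose, 12 fell and 295 did not pass, or 8 and 5 adjusted over the list alone. ZNF804A rose from 0.915 to 1.68 FPKM and ZNF460 from 1.17 to 1.99 FPKM, while ZNF367 fell from 22.7 to 17.0 FPKM and ZNF780A from 13.2 to 10.2 FPKM. The ZNF median was 0.05 and turned to -0.03 under quantile normalization. The ZNF list did not pass (camera adjusted p = 0.101; 0.191 with an estimated correlation), but passed without control replicate 3 (adjusted p = 0.0454), with a filter at a mean of 1 FPKM (0.0453) and by fry (0.0354). Its direction turned under quantile normalization (adjusted p = 0.711) and with the expression trend removed (0.834).

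**Figure D2:**
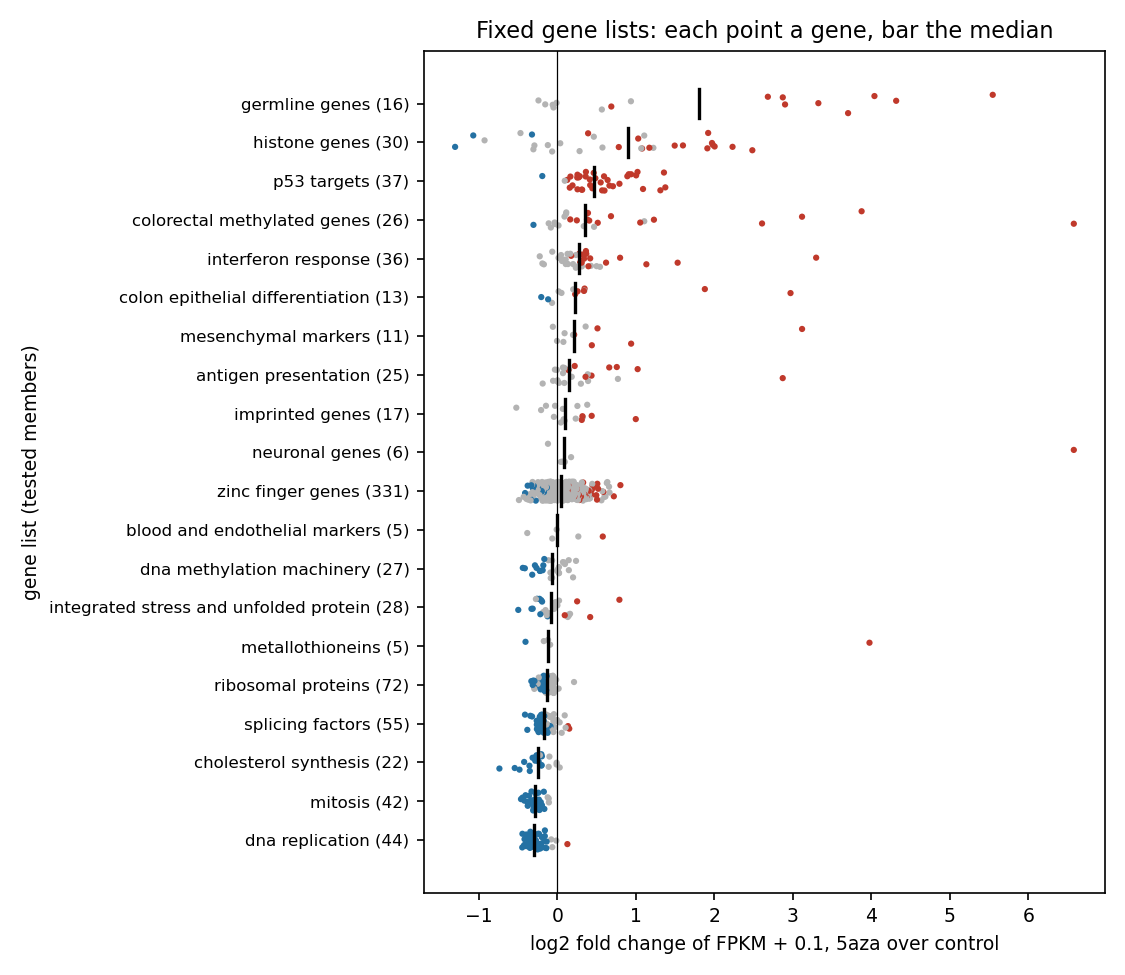
Log2 fold change (5aza minus control) of the tested members of each fixed list, 1 point per gene, with a bar at the list's median; red points rose, blue points fell and grey points did not pass. The p53 list has a median of 0.46, with KITLG alone below 0, and the replication and mitosis lists have medians of -0.30 and -0.29; the ribosomal median moves to -0.00028 under quantile normalization, and the medians of the ZNF and blood lists change sign under it.

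Genes switched on, from under 0.1 FPKM in all 3 control libraries to 1 FPKM or more in all 3 5aza libraries, numbered 29, and all 29 passed limma's test. None was switched off. Of the 29, 23 are annotated genes. Besides CCL20, UCHL1, ZFP42, DAZL, SYCP3, MT1A and COL6A3, they include genes of the early embryo or germline, namely DUX4, TRIM43, TRIM43B, DPPA2, KHDC3L, RFPL4B and PRAMEF12, chosen after their values were seen. Whether such genes are enriched was not tested. The other annotated genes were COL14A1 (means of 0.0245 and 3.95 FPKM), HCLS1 (0.0436 and 3.52 FPKM), COX8C, DCAF4L2, RCN3, FBLN2, LY6D, LAPTM5 and PDLIM4. RFPL4B had means of 0.0127 and 4.68 ± 0.0832 FPKM (n = 3). DUX4, a transcription factor of the early embryo encoded in repeat arrays, had means of 0.00945 and 1.57 ± 0.330 FPKM, and its reads, like those of TRIM43, TRIM43B and PRAMEF12, may come from near-identical copies. The number of genes below 0.1 FPKM in all libraries of a group was 2702 in control and 1799 in 5aza.

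**Figure D3:**
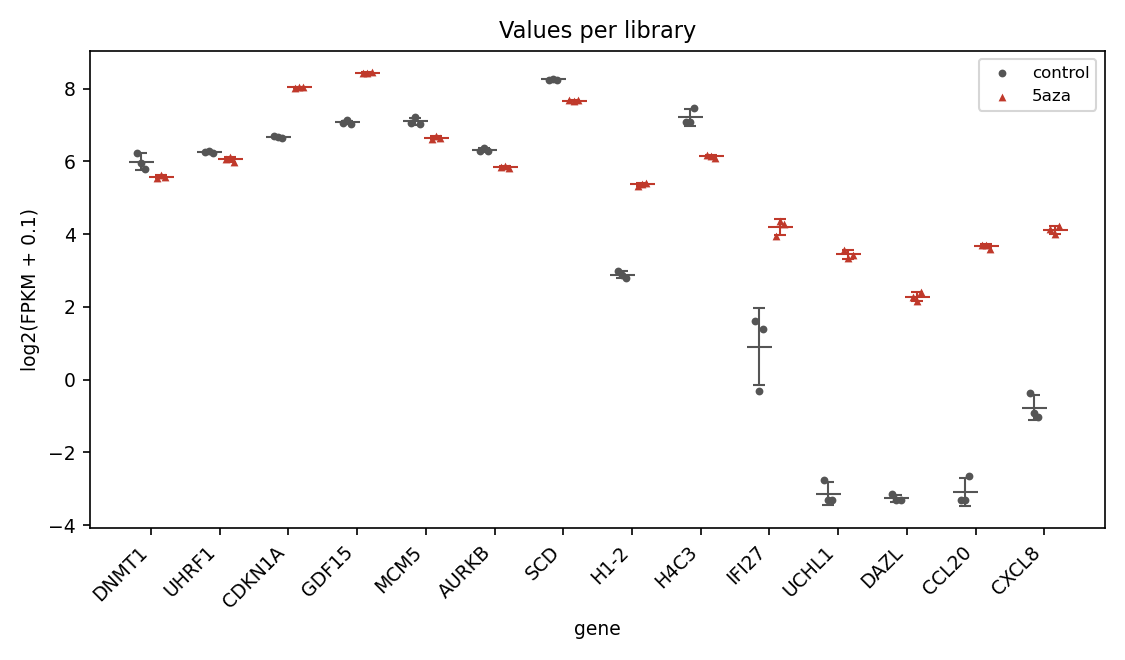
Log2(FPKM + 0.1) of 14 named genes in each of the 3 control (grey circles) and 3 5aza (red triangles) libraries, with the mean and SD of each group. In all 14 genes the groups do not overlap; CCL20 has the largest difference (6.77) and UHRF1 the smallest (-0.19).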

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

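The removal of expression trends and of GC and length trends was chosen after the results were seen. Over all alternatives, 119 of the values of counts stayed within 1.5 times the reported count and 27 did not. Of the lists' values, 405 kept their direction and side of the threshold, 16 lost and 9 gained the call and 7 reversed. Of the 73 named genes, 55 kept their call under each of the 20 alternatives in which they were tested. Some named genes were not tested under all 20, as the filters and the protein-coding limit left them out. Of the 1310 rises and 1619 falls, 1163 and 941 were also called with the expression trend removed, and 1059 and 1136 under quantile normalization.

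Changes of at least 2-fold numbered 115 (114 up, 1 down) with a pseudocount of 1, which shrinks the change of low genes. They numbered 643 (634 up) with no filter, where more genes are tested, and 163 (158 up) with at least 1 FPKM in at least 3 libraries and 124 (120 up) with a mean of at least 1 FPKM, where fewer are. Falls of at least 2-fold numbered 39 under quantile normalization, 2 among protein-coding genes, where unannotated genes are left out, 1 with GC and length trends removed and 2 with the replicate block and those trends removed. All falls numbered 1041 with no variance trend and 972 with the expression trend removed. With an adjusted p under 0.01, 1218 genes changed, 601 up and 617 down. Genes switched on numbered 18 with silence set under 0.05 FPKM, 9 with silence at 0, 71 with expression at 0.5 FPKM and 9 with expression at 2 FPKM. Apart from limits and filters, whose effect lies in their construction, the cause was not tested.

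With 1 library left out, changed genes numbered 1877 to 2599, rises 890 to 1078 and falls 940 to 1521; at least 2-fold, they numbered 254 to 280, with 245 to 273 rises and 7 to 9 falls, and genes switched on 30 to 37. The adjusted p ranged from 0.0454 to 0.168 for the stress list, 0.0300 to 0.151 for the neuronal list and 0.0454 to 0.181 for the zinc finger list, and all 3 passed without control replicate 3 (0.0454), the neuronal list also without 5aza replicate 2 (0.0300).

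With an estimated correlation, the adjusted p was 0.0827 for antigen presentation, 0.0512 for cholesterol synthesis and for histones, 0.0644 for colon epithelium, colorectal methylated genes and replication, 0.0633 for mitosis, 0.171 for methylation machinery, 0.0942 for imprinted genes, 0.124 for mesenchymal genes, 0.240 for ribosomal proteins and 0.0510 for splicing factors. Methylation machinery lost its call with no variance trend (0.0572) and imprinted genes with the replicate block and GC and length trends removed (0.0578). Ribosomal proteins lost theirs under quantile normalization (0.438) and with the expression trend removed (0.567). With no filter, blood markers (0.0160) and neuronal genes (0.0172) passed, the latter also with fry (4.16e-04). Zinc finger genes passed with a mean of at least 1 FPKM (0.0453) and with fry (0.0354), and reversed under quantile normalization (0.711) and with the expression trend removed (0.834). Metallothioneins reversed under quantile normalization (0.981), with the expression trend removed (0.834), with GC and length trends removed (0.775), with the block and those trends removed (0.916) and with fry (0.659). The log2 fold change of ACTB reversed to 0.024 with the expression trend removed. That of GAPDH reversed to 0.050 under quantile normalization, 0.074 with the expression trend removed, and 0.010 with GC and length trends removed, with or without the replicate block. The cause was not tested.

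The labels do not say whether the replicate number pairs the samples. Same-numbered samples' deviations correlated weakly, at 0.048, 0.077 and 0.068. Each sample correlated best with its own number, a hint of pairing from the data and not from the design, so pairing stays unknown. With the replicate block, 2932 genes changed, 1259 up and 1673 down, 276 of them up and 9 down by at least 2-fold. The planned tests on recovered reads were not run, since whole reads were not recovered. Depth limits genes near 0 FPKM, where a few reads decide a value.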

Other observations

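Of the tests below, the comparison with expression-matched lists, the binomial test of 2-fold changes, the test of a uniform background, the pairs with unlike symbols and the test of unannotated genes were chosen after the result was seen, as were the lists of NF-κB and DUX4 targets, whose members' values were not looked at before the test. The binomial test first selected genes on their mean over all 6 libraries, which a rise itself lifts, and the background test first measured genes chosen for their rise; both were replaced. Single genes named below that the fixed rule did not name were chosen after their values were seen.

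The chemokine genes CCL20, CXCL1 and CXCL8 are known targets of NF-κB, and a further list of 28 tested NF-κB target genes that leaves them out rose as well: 19 rose, 0 fell and 9 did not pass in limma's test, and 0 fell at an unadjusted p under 0.05. BIRC3, an inhibitor of apoptosis, rose from 0.930 to 8.40 FPKM (log2 change 3.05, adjusted p = 3.14e-06 in limma's test), CXCL2 to 4.03 FPKM (log2 change 3.81), the adhesion molecule ICAM1 from 2.37 to 6.17 FPKM and the inhibitor NFKBIA from 18.8 to 30.9 FPKM. The acute phase gene SAA1 rose from 0.0655 to 3.23 FPKM, and NFKB1 had means of 15.3 and 14.1 FPKM (adjusted p = 0.157). The list's median log2 fold change was 0.64 (camera p = 5.33e-16 with a preset correlation; p = 0.00224 with an estimated correlation). CXCL2, CXCL5, SAA1, SAA2 and C3 passed the filter on low values through their 5aza values alone. The count of rises, the median and the set test are therefore partly fixed by that choice. BIRC3, ICAM1 and NFKBIA passed it by their control values too. CXCL2, CXCL3 and CXCL5 lie near CXCL1 and CXCL8 on chromosome 4, so their rises may not be independent of the genes that prompted the test. A candidate explanation is an NF-κB response in the 5aza cells, which these data do not tell apart from loss of methylation at each gene.

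DUX4 and several genes known to be its targets, such as TRIM43, TRIM43B and PRAMEF12, were switched on, which may reflect a DUX4 programme. Of 12 further targets that were silent in control libraries, 5 reached at least 0.1 FPKM and 2 times their control mean (exact 95% interval of the share 15.2% to 72.3%), against 20.8% of 2576 other silent genes (one-sided Fisher's exact p = 0.0841). These 5 were ZSCAN4, SLC34A2, CCNA1, RFPL4A and PRAMEF1; ZSCAN4 was listed at 0 in the control libraries and had a mean of 0.750 FPKM in 5aza. Among the listed targets not silent in control libraries, KHDC1L rose from 4.99 to 7.06 FPKM (adjusted p = 0.0117 in limma's test). ZNF280A, RFPL2, CXADR, ZNF705A and SNAI1 did not pass (adjusted p between 0.0689 and 0.522). With 12 genes, the Fisher test leaves the hypothesis open.

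Falls were more frequent among abundant genes (375 of 926 at a mean of 100 FPKM or more, 5 of 940 under 1 FPKM), and genes of replication and mitosis fell together. Against a small shift of all abundant genes as the whole cause, the median of the 86 replication and mitosis genes lay 0.24 below that of expression-matched genes, a difference of -0.236. Its value of -0.29 was below the lowest of 10000 matched lists (-0.12). Matched genes were drawn singly, while replication and mitosis genes move together (estimated correlations 0.237 and 0.212). The matched lists therefore vary too little to give a chance level, and only the size of the difference is used here. With GC and length trends removed, the median of the 86 genes was -0.258, with the lowest matched list at -0.09 under the same limit. That most of the fall stayed argues against GC content or length as the whole cause. For falls as a whole, the number with the expression trend removed was 60.0% of that reported (972 of 1619), so a shift shared by abundant genes and many small falls cannot be told apart, since no outside standard fixes the scale.

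Nearly all changes of at least 2-fold were rises, though quantile normalization gave 39 falls in place of 6. Genes with a control mean of at least 5 FPKM, far from a floor at 0, had 18 such rises and 1 such fall, H4C3 (exact two-sided binomial p = 7.63e-05). That test takes genes as independent, but the rises include the histone genes H1-2, H2BC12 and H2BC5 and the p53 targets CDKN1A and GDF15. Its p therefore overstates the evidence. For the other 250 rises a floor cannot be told apart from loss of silencing. A uniform background in the 5aza libraries would lift alike the 2611 annotated genes silent in control libraries. The 131 that gained most in 2 of the 5aza libraries were measured in the library left out. Their median gain was 0.559 FPKM against a mean of 0.0471 FPKM for the others, a ratio of 11.9 and the lowest of 3. Of the 2611, 57 rose at least 2-fold, and 81.3% had a higher mean in 5aza. Genes chosen as silent in control lean that way by the choice itself, so this share does not measure a background. A small background is not excluded. RNA of blood, endothelial or connective tissue cells would bring their markers. Of 22 markers silent in control libraries, 1 (4.55%), COL6A3, reached 0.5 FPKM in all 3 5aza libraries. Means went from 0.00378 to 0.398 FPKM for THY1, from 0.0580 to 0.299 for CSF1R and from 0.0276 to 0.206 for MMP2. They went from 0.00798 to 0.0650 FPKM for PTPRC and from 0 to 0.0627 for COL1A2, and from 0.0449 down to 0.0403 for KDR. Of 11 tested mesenchymal genes, 5 rose. A limit of 0.5 FPKM cannot exclude a low level of such RNA. Loss of silencing by 5aza stays open and untested, since methylation was not analysed here, and p53 targets such as CDKN1A, GDF15 and MDM2 rose from levels already expressed.

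Genes that rose at least 2-fold lay closer together than expression-matched random sets. Of the 228 annotated genes, 18 neighbouring pairs within 100 kb both rose, against a median of 3 in 10000 random sets (permutation p = 0.0001, the smallest they can give), so a regional effect is consistent with the pairs. Tandem gene families may account for them: without histone pairs and pairs whose symbols share their first 3 letters, 5 pairs were left, against a median of 2 (permutation p = 0.0467, inside the central 95% of random sets). These 5 were DYNLT4 with BTBD19, CD79B with ICAM2, FCGRT with RCN3, ZFP42 with TRIML2 and KHDC3L with OOEP, the last of 1 family in spite of their symbols. Both explanations stay open.

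Of 729 unannotated genes, 40 rose at least 2-fold, against 228 of 11631 annotated genes; within 20 bins of expression, permuting the annotation gave a median of 66 (one-sided permutation p = 1). HBG2, a fetal haemoglobin gene not normally made by colon cells, had means of 179 ± 0.877 FPKM in control and 172 ± 2.20 FPKM in 5aza libraries (SD, n = 3); its annotated span overlaps other genes.

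The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. For each of 3 results, 1 of the 10 splits, the real one, gave a value as large. The real split called 2929 genes, the highest other split 1. At least 2-fold, it called 274 and the highest other split 1. Every other split puts control and 5aza libraries in both groups, so the treatment difference widens the spread within groups. Few calls were therefore bound to follow, and these counts give no chance level. The real split called 15 lists with the preset correlation, and the other splits 6 to 12. Such calls also arise between libraries of mixed groups, which keep part of the treatment difference.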
